A study of Arabidopsis thaliana with 4 samples.

How the data were processed

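Poly-A RNA of calli was sequenced on the BGISEQ-500 platform after pooling the RNA of each group, per the labels' protocols, which also mention biological replicates. Each of the 4 groups had 1 sample. The submitters' processing notes name HISAT, StringTie 1.0.4, Cufflinks, Bowtie2 2.2.5 and Bowtie and the genome build TAIR10, with no role or order. The test behind the authors' calls is not given in the sources used here.

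The deposited files were 6 workbooks, 1 for each pair of the libraries 1A, 2A, 3A and 4A, with 4 sheets each. The log2 fold changes were computed by the authors as the second library over the first, per the file headers, and the p-value and FDR columns beside them were deposited by the authors. All genes of the first sheets had a log2 fold change of at least 1 in size and an FDR under 0.001. The second sheets held genes with a log2 fold change over 3 in size, leaving out 6 to 21 such genes of the first sheet, and the third sheets held the second without the genes whose FDR was listed as 0. The fourth sheets held gene identifiers, and 1 of them also held the authors' list of 108 genes related to photosynthesis. The codes match no sample label, so no library was assigned to a treatment and every comparison is given by code. A further 36 columns of per-library values under these codes were not used, since they could not be tied to a sample. For that reason the depth of each library was not determined here and no interval for counting error is given.

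Gene identifiers were matched to the TAIR10.1 reference table for symbols and locus tags only, and no coordinates were used. Every identifier matched except those of transcripts that the authors named as additions to the annotation, which numbered 45 to 79 per table. Before the data were examined, 20 lists with 280 genes were fixed, covering pigment pathways, photosynthesis, abscisic acid and salt responses, auxin response, cell types of the root and stress responses, and all 280 genes matched the reference. For each comparison the list members that the authors called higher or lower were counted. For lists with at least 3 listed members the median log2 fold change was set against 10000 random lists of the same size from the other listed genes of that table. These could not be matched on expression, because the per-library values were not used. Fisher's exact tests on the counts were computed as planned but are not printed, since genes are not replicates. The genes named were fixed by rule as the 6 highest and 6 lowest genes with a symbol in each comparison, and up to 4 members of each list with the largest fold changes, of which the text prints a part. Other genes named without being in that set, such as the most extreme ones with folds that are not whole numbers, were chosen after their values were seen.

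A fold change was called a whole number when its fold was within a relative tolerance of 1e-09 of one. On simulated ratios of values with 2 decimals, the rule called 100% of the folds over a smallest value and 0.35% of the other folds whole for the comparison of 2A with 1A. The first share follows by construction. The other folds held no values near the smallest one, so the rate of whole folds among low levels was not tested. The random-list step was tested against random lists from the 6139 genes of the same table. There, 20 of 20 simulated lists, with values set to a known shift plus small noise, lay beyond 950 of 1000 random lists. In the 6356 genes of the comparison of 4A with 3A, 17 of 20 did so. The simulated lists lacked the spread of real lists and were all of the same size. The shares may therefore not hold for lists with wide spread or few members. Of 20 lists drawn from the table without a shift, 1 lay beyond 975 of 1000 random lists for 2A with 1A, 0 for 4A with 3A, and 2 in the 3730 genes of 3A with 1A.

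Differences from the planned design followed from the files. The ratios of levels, the filters on low values, the pseudocounts and the scaling planned for level tables were not computed, because the per-library values were not used. The planned difference of the salt responses with and without 2,4-D needs assigned libraries and was not computed. In its place, comparisons sharing no library were set side by side. The alternatives tried were a 4-fold threshold and an FDR limit, and, chosen after seeing the data, lists without whole-number folds, without the added transcripts, and the third sheets of the workbooks. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.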

Results

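RNA sequencing was performed on calli of Arabidopsis thaliana, ecotype Col-0. A callus is a mass of dividing plant cells grown in culture. The calli had been raised from root pieces of 30-day-old plants on medium with 0.5 mg/L of 2,4-D, a synthetic auxin, and moved to fresh medium every 3 weeks. There were 4 groups with 1 sample each. They were calli on Murashige and Skoog medium without treatment, with 2,4-D, with 100 mM NaCl, and with both NaCl and 2,4-D, with salt applied for 4 weeks. The study concerned salt-responsive genes linked to pigment metabolism. RNA of each group had been pooled, so no group had a measured spread between samples and the differences below have no replicate check.

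The values used were fold changes between 4 libraries named only by the codes 1A, 2A, 3A and 4A. No label ties a code to a treatment, so each comparison is reported by code, and the salt response with and without 2,4-D could not be assigned to any pair of libraries. The depth of the libraries was not determined here. Each of the 6 tables listed only the genes that the authors called changed, with a log2 fold change of at least 1 in size and an FDR under 0.001. These calls compare pairs of libraries, not conditions. A total of 11508 genes were listed at least once. In each set of 3 libraries the fold changes of genes listed in all 3 comparisons added up within 1e-09, over 938 to 1184 genes, so the 6 tables hold 3 independent contrasts.

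Many of the largest fold changes were whole numbers, within a relative tolerance of 1e-09. Between 2A and 1A, 79.3% of the 593 genes that differed more than 64-fold had a whole-number fold, against 0.683% of the 3076 genes that differed less than 4-fold. Genes with whole-number folds are therefore named below without a fold. List medians include them unless stated otherwise. Folds that are not whole numbers can also rest on a low level in a library, which was not checked because the per-library values were not used.

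**Figure D1:**
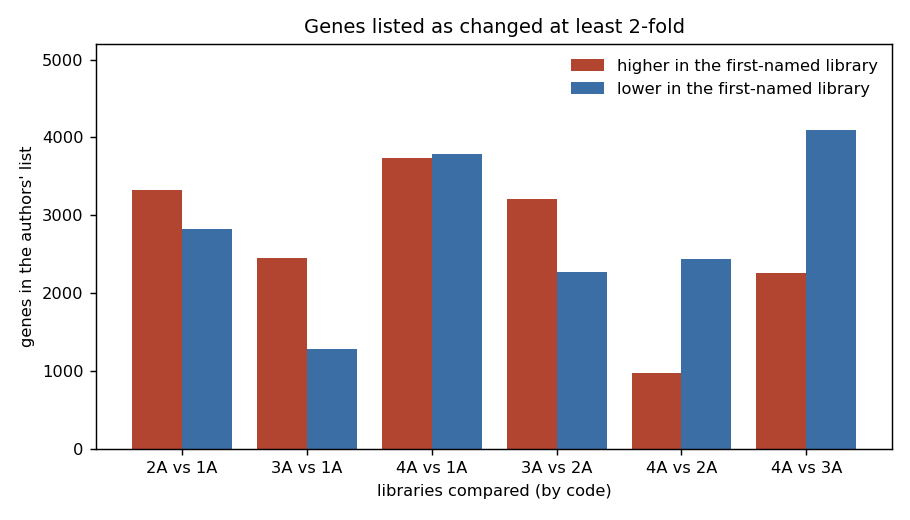
Number of genes in the authors' lists of changed genes for each pair of libraries, with genes higher (red) and lower (blue) in the first-named library. The comparison of 4A with 1A listed the most genes, 3741 higher and 3790 lower, and that of 4A with 2A the fewest, 976 higher and 2444 lower.

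Library 2A differed from library 1A by lower transcripts of the photosynthetic apparatus and higher transcripts of auxin-responsive and root meristem genes. Of the 29 nuclear photosynthesis genes on the list, 28 were lower in 2A and 0 were higher, and of the 25 auxin-response genes 22 were higher and 0 lower. The light-harvesting protein genes LHCB2.2 and LHCB2.1 had log2 fold changes of -8.55 and -6.63 in the authors' deposited table, and RBCS3B, a small subunit of Rubisco, had -6.23. GH3.3 and GH3.2, which encode enzymes that conjugate auxin to amino acids, had log2 fold changes of 10.87 and 10.60 in the authors' deposited table. In all, 3318 genes were higher in 2A and 2821 were lower.

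The median log2 fold change of the listed photosynthesis genes was -4.64, below the medians of all 10000 random lists of the same size drawn from this table. LHCB1.1 stood at -5.76 in the authors' deposited table, and the list ranged down to LHCB2.2 from -2.78 for RCA, the activase of Rubisco. Copies of LHCB1, LHCB2 and RBCS are nearly identical, so the share of reads assigned to each copy is uncertain. Chlorophyll biosynthesis genes followed the same direction, with 15 of 24 members lower and 0 higher. Among them were CHLI2, a subunit of magnesium chelatase, at a log2 fold change of -4.14, CRD1, a cyclase subunit, at -3.94, and PORB, a protochlorophyllide reductase, at -3.06 in the authors' deposited table. GUN4, an activator of magnesium chelatase, was lower with a whole-number fold. Of the 10 chlorophyll breakdown genes, only CLH1 was listed, as lower with a whole-number fold.

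Carotenoid genes split, with 8 of 21 lower and 3 higher, a direction that turned at a 4-fold threshold, where 2 were lower and 3 higher. LUT2, the lycopene epsilon-cyclase, had a log2 fold change of -2.60 in the authors' deposited table, whereas BCH2, a beta-carotene hydroxylase, had 2.88 and NCED5, a cleavage enzyme of abscisic acid synthesis, had 4.31. Flavonoid genes showed 4 of 20 members higher and 1 lower. The flavonol synthase gene FLS1 was at 2.21 and the glycosyltransferase gene UGT75C1 at 1.98 in the authors' deposited table, with F3H, a flavanone hydroxylase, at -1.48. Among 16 genes on the anthocyanin regulator list, 6 were higher and 0 lower. They included MYB12, known as a regulator of flavonol synthesis, at 5.13 and EGL3 at 3.07 in the authors' deposited table, and GL3 with a whole-number fold. The other higher members were LBD37 at 1.92, LBD38 at 1.56 and LBD39 at 3.06 in the authors' deposited table, which are known as repressors of anthocyanin synthesis. At the entry to phenylpropanoid synthesis, 4 of 8 genes were lower, with PAL3 at -4.04 and 4CL1 at -2.31 in the authors' deposited table.

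The auxin-response members that were higher in 2A included IAA19 and IAA1, auxin-inducible repressors, at log2 fold changes of 8.92 and 7.19 in the authors' deposited table. LBD18 and GH3.1 were higher with whole-number folds. The median of the 22 members was 5.24, or 3.96 without whole-number folds, and no random list of 10000 had a higher median than the full list. All 6 root meristem genes were higher, among them the stem cell regulators WOX5 at 5.91 and SHR at 4.65 in the authors' deposited table, with BBM, PLT1 and PLT2 at whole-number folds, leaving 3 without them. Root hair markers were higher for 6 of 7 genes, with RHD6 at 7.11 and COBL9 at 3.55 in the authors' deposited table. Of the 8 phosphate starvation genes 7 were higher, including MGD3, a galactolipid synthase, at 4.65 and SPX3 at 4.06 in the authors' deposited table.

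Defence genes were lower for 6 of 9 members, and all 10000 random lists had a higher median than theirs. PR2, a glucanase, had a log2 fold change of -7.32, LOX2, a lipoxygenase of jasmonate synthesis, -6.62, and PAD3, the last enzyme of camalexin synthesis, -4.31 in the authors' deposited table. The abscisic acid and dehydration list split, with 7 of 27 members lower, such as COR15A at -6.63 and LEA4-5 at -4.44, and 2 higher, RD22 at 8.41 and LTI30 at 2.81 in the authors' deposited table. Of 11 sodium and potassium transport genes 3 were listed, all higher: SOS3, a calcium sensor of the salt overly sensitive pathway, at 6.78, HAK5, a potassium transporter, at 5.38, and AVP1 at 1.16 in the authors' deposited table. SOS3 had whole-number folds against 1A in 3A and 4A, so its value here may also rest on a low level in 1A. Of the remaining lists, redox genes were higher for 5 and lower for 3 of 13, cell cycle genes higher for 4 of 14, xylem markers higher for 4 and lower for 1 of 6, endodermis markers higher for 4 of 9 (2 without whole-number folds), senescence genes higher for 3 and lower for 2 of 7, and heat shock genes higher for 4 of 10. At a 4-fold threshold the redox and senescence lists turned, each with 1 gene higher and 2 lower.

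Among genes with a symbol, the 6 highest in 2A were LTP3 (gene ID 836051), GH3.1 (815985), RGF8 (814909), MAKR6 (835367), WOX11 (821196) and LBD18 (819150). The 6 lowest were JAL23 (818518), THI2.1 (843558), MBP1 (841633), RALFL32 (827037) and the small nuclear RNA genes U2.11 (28716172) and U2.1 (28716281). All 12 had whole-number folds. Outside that set, CKX3, a cytokinin oxidase, was at a log2 fold change of 10.06, EARLI1 at -10.77 and BGLU18, a beta-glucosidase of ER bodies, at -9.60 in the authors' deposited table.

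Endodermis and root meristem transcripts were listed as higher in library 3A than in library 1A. So were heat shock, flavonoid, dehydration and auxin-response transcripts, with a smaller set of photosynthesis transcripts lower. All 10 heat shock genes were higher in 3A, as were 13 of 27 abscisic acid and dehydration genes, 7 of 20 flavonoid genes and 8 of 9 endodermis and suberin markers, and no member of these lists was lower. The dehydration gene RD22 had a log2 fold change of 6.91 in the authors' deposited table, and the flavonoid genes FLS1 and CHS, the chalcone synthase, had 4.89 and 3.45. In all, 2449 genes were higher in 3A, or 65.7% of those listed, and 1281 were lower.

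Small heat shock protein genes led the heat shock list, with HSP17.6C at a log2 fold change of 3.94 and HSP18.2 at 3.57 in the authors' deposited table. HAI2, a phosphatase of abscisic acid signalling, was at 5.50 and RD20 at 5.46 in the same authors' deposited table, while RAB18 and RD29B were higher with whole-number folds. The median of the dehydration list was 2.47, above 9615 of 10000 random lists. CHIL and CHI of the chalcone isomerase family stood at 3.64 and 2.70 in the authors' deposited table, and SCPL10, an acyltransferase-like gene, was higher with a whole-number fold. Genes on the anthocyanin regulator list were higher for 5 of 16, with EGL3 at 4.93 and the flavonol regulator MYB12 at 3.28 in the authors' deposited table. The repressors LBD37 and LBD39 were at 1.22 and 1.59 in the authors' deposited table. CASP4, a membrane protein of the Casparian strip, was at 4.25 and GPAT5, a suberin enzyme, at 4.34 in the authors' deposited table, with CASP1 and CASP2 at whole-number folds.

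Photosynthesis genes were lower for 8 of 29, with a median log2 fold change of -1.22, below that of 9326 of 10000 random lists, and 0 of them reached a 4-fold difference. LHCB1.3 was at -1.57 and LHCB2.2 at -1.39 in the authors' deposited table. Only 1 of 24 chlorophyll biosynthesis genes was listed, PORC at 1.28, and only 1 of 10 chlorophyll breakdown genes, HCAR at 1.22 in the authors' deposited table. Carotenoid genes were higher for 3 of 21, with NCED2 at 3.93, NCED3 at 1.65 and ABA4 at 1.53 in the authors' deposited table. NCED2 had whole-number folds against 1A in 2A and 4A, so its value here may also rest on a low level in 1A. The sodium transporter gene HKT1 and the calcium sensor gene SOS3 were the listed members of the transport list, both higher with whole-number folds.

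Auxin-response genes were higher in 3A for 9 of 25, with LBD16 at a log2 fold change of 3.64 and GH3.3 at 3.06 in the authors' deposited table. All 6 root meristem genes were higher, including WOX5 at 3.19 in the authors' deposited table, with BBM, PLT1 and PLT2 at whole-number folds, leaving 3 without them. Redox genes were higher for 5 of 13 and lower for 1, with the ascorbate peroxidase gene APX2 at 3.56 and the superoxide dismutase gene CSD2 at 3.19 in the authors' deposited table. Senescence genes were lower for 3 of 7, with SAG13 at -3.31 and SEN1 at -2.77, and defence genes for 3 of 9, with LOX2 at -4.04 in the authors' deposited table. Phosphate starvation genes split, with PHT1;1, a phosphate transporter, at 4.61 and SPX1 at -2.24 in the authors' deposited table, and SPX3 lower with a whole-number fold. Root hair markers were higher for 3 of 7, xylem markers for 1 of 6, and phenylpropanoid entry genes were higher and lower for 1 each of 8. No cell cycle gene was listed.

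The 6 highest genes with a symbol were LTP3, CASP1 (818183), AAE2 (844060), BS1 (843791), OFP14 (844336) and DGR2 (832620), and the 6 lowest were U2.11, DND1 (831393), ACBP1 (835428), MRU1 (833513), U2.7 (3771548) and OFP9 (825715). All 12 had whole-number folds. Among the other genes MSL4, a mechanosensitive channel, was at a log2 fold change of 8.11, the amino acid permease AAP2 at 6.64 and the alpha-amylase AMY1 at -5.92 in the authors' deposited table.

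Library 4A differed from library 1A by lower photosynthesis, chlorophyll and defence transcripts together with higher auxin-response, meristem and heat shock transcripts. Photosynthesis genes were lower for 28 of 29 and higher for 0, chlorophyll biosynthesis genes were lower for 12 of 24, and 17 of 25 auxin-response genes and all 10 heat shock genes were higher. RBCS3B had a log2 fold change of -9.67, LHCB2.2 -9.65 and PSBQ2, a photosystem II subunit, -7.77 in the authors' deposited table. The chalcone synthase gene CHS, the first enzyme of flavonoid synthesis, was at -4.83 in the authors' deposited table, while 3 other flavonoid genes were higher. In all, 3741 genes were higher in 4A and 3790 were lower.

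The photosynthesis median was -5.45, below those of all 10000 random lists, and the chlorophyll biosynthesis median was -3.74, below those of 9990. CHLH, the large subunit of magnesium chelatase, was at -4.35 and PORB at -4.12 in the authors' deposited table. Chlorophyll breakdown genes were lower for 4 of 10, with RCCR at -2.40 and SGR2 at -1.65 in the authors' deposited table. Carotenoid genes split with 3 higher, such as BCH2 at 3.96, and 5 lower, such as NCED9 at -3.92 in the authors' deposited table. Phenylpropanoid entry genes were lower for 4 of 8, including PAL4 at -3.27 in the authors' deposited table. On the anthocyanin regulator list 5 of 16 were higher, including the flavonol regulator MYB12 at 4.35 in the authors' deposited table. The repressors LBD37 and LBD39 were at 1.40 and 1.92 in the authors' deposited table.

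GH3.2 and IAA19 had log2 fold changes of 10.37 and 8.31 in the authors' deposited table, and the median of the auxin-response list was 6.35, or 4.25 without whole-number folds. All 6 root meristem genes were higher, with WOX5 at 6.54 and SCR at 3.35 in the authors' deposited table, with BBM, PLT1 and PLT2 at whole-number folds, leaving 3 without them. HSP17.6A was at 3.45 and the disaggregase gene HSP101 at 3.09 in the authors' deposited table. The dehydration list split evenly, 8 higher and 8 lower, with RD22 at 8.65, HAI2 at 4.50, COR15A at -5.63 and COR47 at -3.14 in the authors' deposited table. Defence genes were lower for 6 of 9, with VSP2, a vegetative storage protein gene, at -8.95 and PR2 at -3.46 in the authors' deposited table, and for 3 without whole-number folds. HAK5 was at 5.72 and the calcium exchanger gene CAX1 at -2.36, and root hair markers were higher for 5 of 7, with RHD6 at 8.56 in the authors' deposited table.

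Cell cycle genes divided in 4A, with 4 of 14 higher, such as the ribonucleotide reductase gene RNR1 at 2.30 and the replication gene MCM2 at 2.00, and 6 lower, such as CDKB2;2 at -1.68 and KNOLLE, a syntaxin of cell division, at -1.61 in the authors' deposited table. Senescence genes were higher for 4 of 7 and lower for 2, with NAC092 at 4.13 and WRKY53 at -6.13 in the authors' deposited table. Phosphate starvation genes were higher for 5 of 8, redox genes higher and lower for 4 each of 13, xylem markers higher and lower for 2 each of 6, and endodermis markers higher for 1 of 9. At a 4-fold threshold the direction turned for flavonoid genes, with 0 higher and 1 lower, carotenoid genes, with 3 higher and 1 lower, and cell cycle genes, with 1 higher and 0 lower. The 6 highest genes with a symbol were LTP3, GH3.1, RGF8, LBD18, BBM (831609) and MAKR6, and the 6 lowest were JAL23, MBP1, U2.11, RALFL32, AMY1 (828603) and MBP2 (841632). Of these only MBP2, a myrosinase-binding protein, lacked a whole-number fold, at a log2 fold change of -11.52 in the authors' deposited table.

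Library 3A had higher photosynthesis, chlorophyll and dehydration transcripts than library 2A and lower auxin-response and meristem transcripts. Photosynthesis genes were higher for 28 of 29, chlorophyll biosynthesis genes for 16 of 24, while 20 of 25 auxin-response genes and all 6 meristem genes were lower. LHCB2.2 was at a log2 fold change of 7.16, PSAD1, a photosystem I subunit, at 4.95 and PORB at 3.87 in the authors' deposited table. In all, 3204 genes were higher in 3A and 2272 were lower.

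The photosynthesis median was 4.12, above those of all 10000 random lists, and the auxin-response median was -3.01, below all of them. The chlorophyll biosynthesis and dehydration medians lay above 9849 and 9926 of 10000 random lists, and the root meristem median below 9985. GH3.3 was at -7.81, LBD18 at -6.39 and PLT1, a root stem cell factor, at -4.04 in the authors' deposited table. Carotenoid genes were higher for 10 of 21 and lower for 2, and at a 4-fold threshold for 2 each. LUT2 was at 3.29 and ZEP, the zeaxanthin epoxidase, at 1.88 in the authors' deposited table, against BCH2 at -2.73, and NCED5 was lower with a whole-number fold. Chlorophyll breakdown genes were higher for 4 of 10, with SGR1, the magnesium dechelatase, at 1.23 in the authors' deposited table. Flavonoid genes were higher for only 6 of 20, with a median above 9493 of 10000 random lists, and with F3H at 3.53 and CHS at 2.98, and phenylpropanoid entry genes for 3 of 8, with 4CL3 at 6.01 in the authors' deposited table. Genes on the anthocyanin regulator list were lower for 4 of 16 and higher for 1, EGL3 at 1.86 in the authors' deposited table. The lower ones were GL3 at -2.11, the flavonol regulator MYB12 at -1.85 and the repressors LBD39 and LBD38 at -1.47 and -1.26.

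Dehydration genes were higher in 3A for 16 of 27, with COR15A at 6.16 and HAI1 at 2.84, and lower for 1, RD22 at -1.50 in the authors' deposited table. Heat shock genes were higher for 9 of 10, with HSP17.6C at 3.69 and HSP22 at 3.65, and defence genes for 5 of 9, with PR2 at 5.64 and PAD3 at 4.17 in the authors' deposited table. Endodermis markers were higher for 5 of 9, with CYP86A1, a suberin hydroxylase, at 3.83 and CASP4 at 2.68 in the authors' deposited table. HKT1 was higher with a whole-number fold, while HAK5 and SOS3 were at -5.14 and -2.39 in the authors' deposited table. Phosphate starvation genes were lower for 6 of 8, with MGD3 at -5.49 and the transporter PHT1;4 at -4.22 in the authors' deposited table. Senescence genes were lower for 4 of 7 and higher for 2, redox genes higher for 4 of 13 and lower for 1, xylem markers lower for 3 of 6, root hair markers lower for 2 of 7 and cell cycle genes higher for 2 of 14. The 6 highest genes with a symbol were RALFL32, CM2 (830954), THI2.1, TPS12 (826958), NAS1 (830377) and JAL23, and the 6 lowest were SPX3 (819120), IPS1 (820152), DREB19 (818414), U11/U12-31K (820203), CYP705A27 (841474) and WIP4 (821637), all with whole-number folds.

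Library 4A differed least from library 2A by the number of listed genes, with 976 higher and 2444 lower. Heat shock genes were higher in 4A for 9 of 10 and root hair markers for 4 of 7, whereas phosphate starvation genes were lower for 6 of 8. HSP22 was at a log2 fold change of 2.80, the heat shock factor gene HSFA2 at 2.27 and the root hair gene COBL9 at 1.78 in the authors' deposited table. SPX3 was at -3.14 and CHS at -5.30 in the authors' deposited table.

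The heat shock median was 2.01, above those of all 10000 random lists from this table, and the phosphate starvation median was -2.45, above those of 1120. Flavonoid genes were lower for 4 of 20, with FLS1 at -1.80 and CHI at -1.32 in the authors' deposited table. Photosynthesis genes were lower for 9 of 29 and higher for 1, with RBCS3B at -3.44, PSBQ2 at -2.81 and LHCB2.1 at 1.13 in the authors' deposited table, and their median of -1.58 exceeded 4123 of 10000 random medians. Chlorophyll biosynthesis genes were lower for 2 of 24, CHLH at -1.44 and PORB at -1.06, and RCCR of chlorophyll breakdown was at -1.44 in the authors' deposited table. Carotenoid genes were higher for 1 of 21 and lower for 2, with BCH2 at 1.07 and NCED5 at -1.70 in the authors' deposited table. PAL4 at -1.18 was the listed phenylpropanoid gene in the authors' deposited table. The repressors LBD39 at -1.14 and LBD38 at -1.06 were the listed members of the anthocyanin regulator list.

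Dehydration genes were higher in 4A for 5 of 27 and lower for 2, with DREB2A, a drought and heat regulator, at 2.03, the proline synthesis gene P5CS1 at 1.35 and COR47 at -2.61 in the authors' deposited table. Of the transport genes, SOS1, the plasma membrane sodium exchanger, was at 1.22, the vacuolar exchanger gene NHX2 at 1.43, AKT1 at -1.33 and CAX1 at -1.78 in the authors' deposited table. Auxin-response genes were lower for 5 of 25 and higher for 1, with IAA3 at -2.60, and SHR of the meristem list was at -2.63 in the authors' deposited table. Defence genes split, with PR2 at 3.86 and VSP2 at -5.24, as did senescence genes, with SEN1 at 3.15 and WRKY53 at -3.79 in the authors' deposited table. Xylem markers were lower for 3 of 6, endodermis markers for 2 of 9, cell cycle genes for 2 of 14, and redox genes lower for 2 of 13 and higher for 1, with APX2 at 2.43 in the authors' deposited table. At a 4-fold threshold the dehydration list turned, with 1 higher and 2 lower, as did the redox list, with 1 higher and 0 lower. The 6 highest genes with a symbol were CM2, JOSL (817514), MEF8S (829380), PP2-B8 (814765), PSAD-2 (838400) and CYP98A8 (843795), and the 6 lowest were EXO70H7 (836094), IPMI1 (825068), BUD2 (832011), DRT101 (831926), ADT6 (837345) and TLL1 (841089), all with whole-number folds.

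Library 4A had lower photosynthesis, chlorophyll and defence transcripts than library 3A and higher auxin-response and meristem transcripts. Photosynthesis genes were lower for 28 of 29, chlorophyll biosynthesis genes for 14 of 24, flavonoid genes for 7 of 20 and carotenoid genes for 10 of 21, with 2 carotenoid genes higher. Auxin-response genes were higher for 14 of 25 and meristem genes for 5 of 6, with none lower on either list. CHS was at a log2 fold change of -8.28, RBCS3B at -8.61, GUN4 at -6.63 and GH3.2 at 7.46 in the authors' deposited table. In all, 2260 genes were higher in 4A, or 35.6% of those listed, and 4096 were lower.

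The photosynthesis median of -4.76 lay below those of all 10000 random lists, whereas the flavonoid median of -3.12 lay below 9308. The carotenoid median of -1.55 lay below only 5642, and at a 4-fold threshold 3 carotenoid genes were lower and 2 higher. The carotenoid list thus did not stand out from the other listed genes. The dehydration and endodermis medians lay below 8806 and 9114. FLS1 was at -4.49, CHI at -3.46 and SCPL10 at -3.12 in the authors' deposited table. CHLH was at -5.02 and PORC at -5.01, while BCH2 was at 3.80 and PSY, phytoene synthase, at -2.06 in the authors' deposited table. RCCR and CLH1 were the 2 listed chlorophyll breakdown genes, both lower. Phenylpropanoid entry genes were lower for 5 of 8, with 4CL3 at -5.01, and the anthocyanin regulators GL3 and EGL3 were at 2.44 and -1.44 in the authors' deposited table.

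Dehydration genes were lower in 4A for 11 of 27 and higher for 2, with COR15A at -5.16 and RD29A at -4.52 in the authors' deposited table. HKT1 was lower with a whole-number fold, whereas HAK5 was at 5.48 in the authors' deposited table. Endodermis markers were lower for 7 of 9, with CYP86A1 at -3.90 and CASP2 at -3.76, and defence genes for 5 of 9, with VSP2 at -8.67 in the authors' deposited table. Without whole-number folds 2 defence genes were lower. LBD18 was at 6.56, PLT1 at 4.26 and PLT2 at 4.07 in the authors' deposited table. Root hair markers were higher for 5 of 7 and lower for 1, with RHD6 at 4.71, and phosphate starvation genes were higher for 5 of 8, with MGD3 at 2.75 in the authors' deposited table. Senescence genes were higher for 4 of 7, with SEN1 at 5.66, and lower for 2, with WRKY53 at -5.57 in the authors' deposited table. Heat shock genes were listed for HSP90.1 at 1.66, HSP17.6C at -1.47 and HSP18.2 at -1.41 in the authors' deposited table. Cell cycle genes were higher for 4 and lower for 6 of 14, redox genes higher for 1 and lower for 4 of 13, and xylem markers higher for 2 and lower for 1 of 6, which turned at 4-fold to 0 higher and 1 lower. The 6 highest genes with a symbol were DREB19, CYP705A27, U11/U12-31K, emb1796 (824085), WIP4 and PIRL8 (828711), all with whole-number folds. The 6 lowest were IPMI1, RALFL32, DR4 (843668), SBT4.12 (836026), bZIP (843221) and GER2 (833914), of which only DR4 lacked a whole-number fold, at a log2 fold change of -12.21 in the authors' deposited table.

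**Figure D2:**
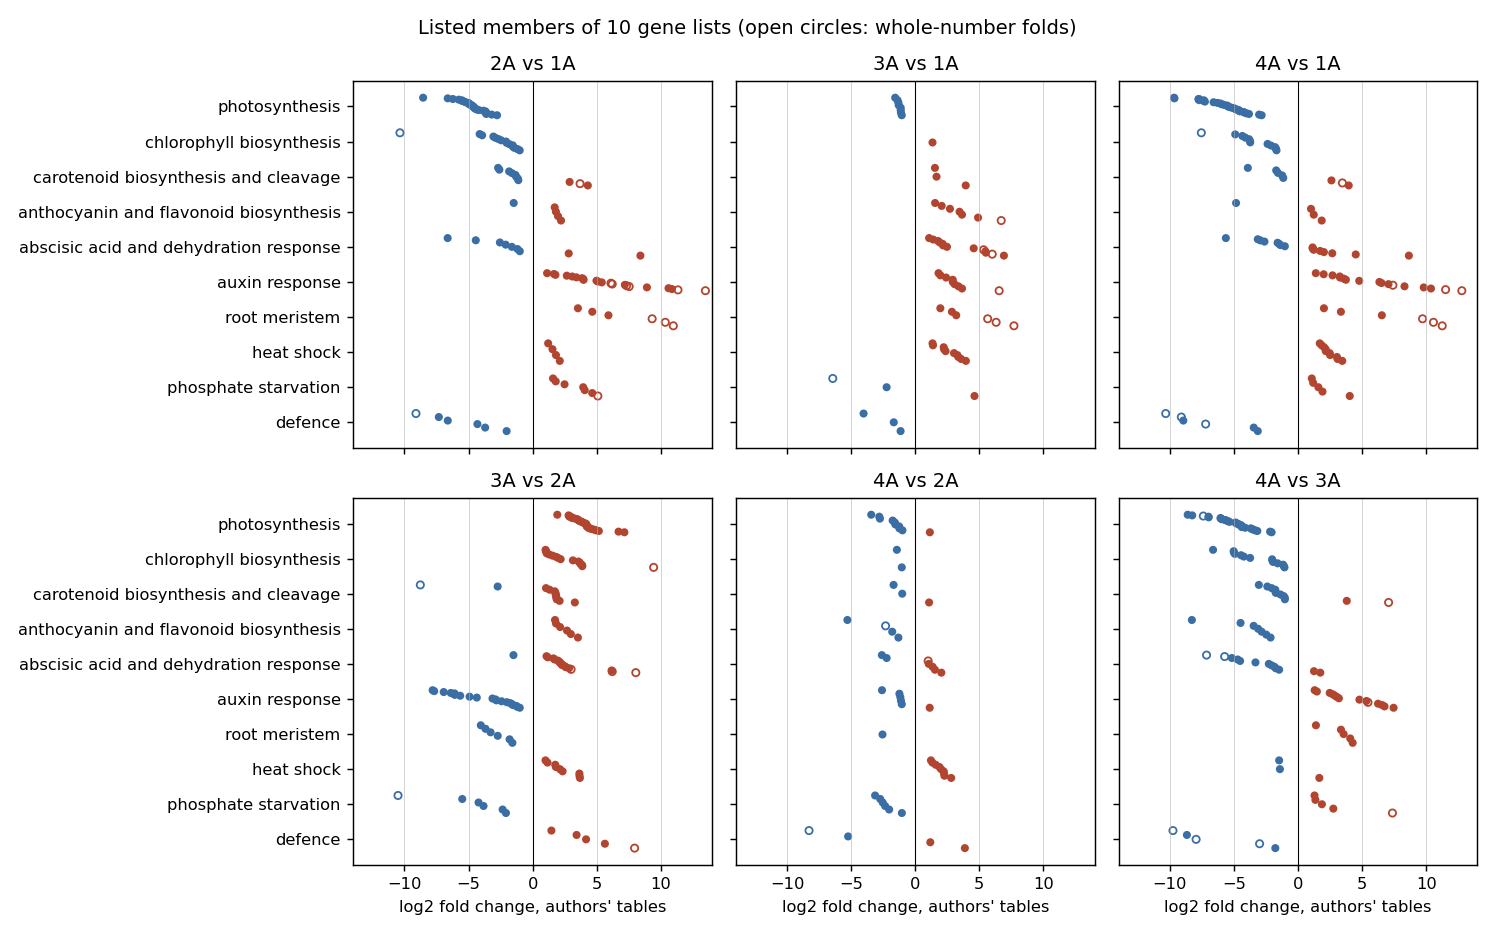
Log2 fold changes from the authors' tables for the listed members of 10 gene lists, one panel per pair of libraries, with red points higher and blue points lower in the first-named library and open circles for whole-number folds. All 28 listed photosynthesis genes lie below 0 for 2A against 1A, 4A against 1A and 4A against 3A, and above 0 for 3A against 2A.

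Comparisons that share no library were set side by side, because comparisons with a library in common share its chance values. Of the 3482 genes listed both for 2A against 1A and for 4A against 3A, 87.5% had the same direction, where the shares of higher genes in each would give 50.5%. All 28 photosynthesis genes listed in both were lower in 2A and in 4A, as were all 13 chlorophyll biosynthesis genes and all 5 defence genes. All 14 auxin-response genes, all 5 root meristem genes and all 5 phosphate starvation genes listed in both were higher in 2A and in 4A. Flavonoid genes parted, with 3 of 4 in opposite directions, and all 3 endodermis markers did likewise. Of the 1247 genes listed both for 3A against 1A and for 4A against 2A, 43.9% had the same direction, where 41.6% would follow from the shares, and 30.9% against 32.3% among genes that differed 4-fold in both. All 9 heat shock genes listed in both were higher in 3A and in 4A, while all 4 flavonoid genes went in opposite directions. Of the 3280 genes listed both for 4A against 1A and for 3A against 2A, 10.2% had the same direction against 48.2% from the shares. Because the fold changes add up across libraries, this pairing largely restates the first and is no further evidence. Only genes listed in both tables enter these shares, and genes are not replicates.

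**Figure D3:**
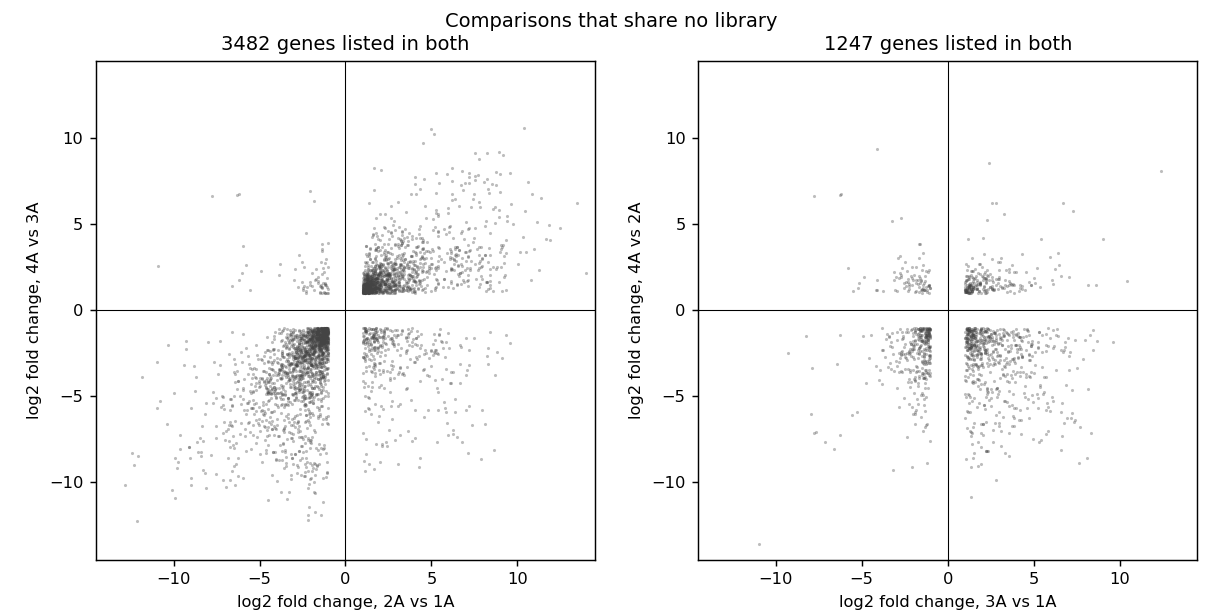
Log2 fold changes from the authors' tables for genes listed in both of a pair of comparisons that share no library, 1 point per gene. On the left, 2A against 1A is on the horizontal axis and 4A against 3A on the vertical axis, and 1290 genes were higher and 1756 lower in both; on the right, 3A against 1A is on the horizontal axis and 4A against 2A on the vertical axis, and 226 were higher and 321 lower in both.

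Several pigment genes were listed in none of the 6 comparisons analysed here. They included the late anthocyanin enzyme genes DFR, LDOX and UGT79B1, the regulators MYB75, MYB90, TT8 and TTG1, the chlorophyll breakdown genes PAO and PPH, and the carotenoid genes PDS3 and CCD4. A gene missing from a list of changed genes was either below the thresholds or not tested, and the tables do not tell these apart.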

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

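With a threshold of 4-fold, planned beforehand, genes higher and lower numbered 1698 and 1365 for 2A against 1A, 1271 and 487 for 3A against 1A, 1596 and 2225 for 4A against 1A, 1481 and 955 for 3A against 2A, 242 and 1229 for 4A against 2A, and 878 and 2430 for 4A against 3A. In the third sheets of the authors' workbooks, an alternative chosen after seeing the data, the numbers were 1047 and 631, 781 and 215, 867 and 1288, 692 and 433, 110 and 679, and 397 and 1436 in the same order. Both settings keep fewer genes by construction. An FDR limit of 0.001 removed no gene, so it says nothing about stability. Leaving out whole-number folds, or the transcripts added to the annotation, kept all 12 counts within 1.5 times, both chosen after seeing the data.

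Further alternatives for the lists were also chosen after seeing the data. Of 95 list results with at least 3 listed members and more in 1 direction, the direction turned at 4-fold for 9, since fewer genes pass. Another 37 moved by over 1.5 times, among them the photosynthesis genes lower in 3A than in 1A, of which 0 stayed, and 49 moved less than that. For 2A against 1A, 2 carotenoid genes stayed lower against 3 higher, 1 redox gene higher against 2 lower and 1 senescence gene higher against 2 lower. For 4A against 1A, 0 flavonoid genes stayed higher, 1 carotenoid gene lower and 0 cell cycle genes lower. For 4A against 2A, 1 dehydration gene stayed higher and 0 redox genes lower, and for 4A against 3A 0 xylem markers stayed higher. Without whole-number folds none of the 95 turned, and 8 moved by over 1.5 times. A tie was not counted as a turn in either setting. The root meristem genes of 2A, 3A and 4A against 1A moved, with 3 higher in each. So did the defence genes of 4A against 1A and 3A, with 3 and 2 lower, and the endodermis markers of 2A against 1A, with 2 higher. The phosphate starvation genes of 3A against 1A became a tie, with 1 lower and 1 higher. Their median went from -2.24 to 1.19. The transport genes of 4A against 1A also tied, with 1 higher and 1 lower. For 3A against 1A beside 4A against 2A, the share with the same direction was 30.9% at 4-fold, under the 32.3% that the shares of higher genes give, and the cause was not tested.

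Filters on low values, pseudocounts and another scaling were not run, because the per-library values under these codes were not used. With no replicates, a difference between 2 libraries cannot be set against a spread. No paired analysis was possible because each group had 1 sample and the codes carry no replicate number.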

Other observations

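The gene groups in these opening paragraphs were chosen after seeing the data. Genes of aliphatic glucosinolate biosynthesis, which makes sulfur-containing defence compounds from methionine, were lower in 4A than in each other library, for 15 of 19 against 1A, 16 against 2A and 17 against 3A, with none higher. Without whole-number folds these counts were 11, 9 and 12. In 3A, 17 were higher than in 1A and none lower. CYP83A1 had a log2 fold change of -11.45, the chain elongation gene MAM1 -10.55 and the aminotransferase gene BCAT4 -10.61 for 4A against 3A in the authors' deposited table. For 2A against 1A, 8 of 19 were lower and 2 higher, with CYP83A1 at -2.12 in the authors' deposited table. ER body and myrosinase-associated genes, which belong to a neighbouring defence system, were lower for 6 of 9 in 2A and for 5 in 3A, both against 1A, and for 7 in 4A against 3A. BGLU18, a major beta-glucosidase of ER bodies, had -9.60, -2.29 and -8.04 in these comparisons in the authors' deposited table. The change was smaller for BGLU23 of the same list, at -1.95 in 2A against 1A and -1.58 in 4A against 3A. BGLU23 was not listed for 3A against 1A.

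Of 14 families taken from the reference product names, a part is given here. Aquaporin genes were higher in 3A than in 1A for 8 of 37 and lower for 1, and lower in 4A than in 3A for 17 and higher for 1. Class III peroxidase genes were lower in 4A than in 3A for 33 of 72 and higher for 7, and higher in 3A than in 2A for 26 and lower for 7. Genes of xyloglucan endotransglucosylases, which loosen cell walls, were lower in 4A than in 2A for 9 of 30 and higher for 0. Small auxin-up RNA (SAUR) genes were higher in 2A than in 1A for 13 of 78 and lower for 6, whereas in 3A against 1A 4 were higher and 11 lower. In 4A against 1A they split, with 8 higher and 9 lower. TIR-NBS-LRR resistance genes were lower in 2A than in 1A for 24 of 91 and higher for 8. Each is a count of the authors' calls, with no test. Of all listed genes, 54.0%, 65.7% and 49.7% were higher in 2A, 3A and 4A against 1A. The shares were 58.5% in 3A against 2A, 28.5% in 4A against 2A and 35.6% in 4A against 3A.

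Of the tests below, those on photosynthesis genes were chosen only after the result was seen. Photosynthesis genes were lower in 2A than in 1A. A uniform difference in scaling between the libraries leaves the order of the genes as it is, so alone it would not set these members apart from other genes listed as lower. Their median log2 fold change was -4.64 against -1.95 for the other lower genes, below the medians of 10000 of 10000 random lists of other lower genes, which speaks against scaling as the whole cause. In the same test on the 8 photosynthesis genes lower in 3A than in 1A, the median lay below only 146. Reads shared between near-identical gene copies could blur single LHCB or RBCS genes. The LHCB1, LHCB2, LHCB4, RBCS, PSBO, PSBP, PSBQ and PSAD members were therefore set aside. Still, the 13 remaining members had a median log2 fold change of -4.68. A difference in the make-up of the calli stays open and was not tested, and no biological explanation was tested because the libraries could not be assigned to treatments.

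Whole-number folds were common among large fold changes. A candidate explanation is that a fixed smallest value stood in for the library with the lower level. Of the 327 genes that were higher in 2A than in 1A with a whole-number fold of at least 64, the prediction made beforehand was whole-number folds also against 1A in the other libraries. Among 333 such pairs of gene and comparison, 95.5% were whole, which is consistent with that explanation. Fold changes of these genes then may rest on that smallest value rather than on a measured level.

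The authors' list of 108 photosynthesis-related genes, which was given beside these comparisons and is not independent evidence, held 65 genes lower and 3 higher in 2A than in 1A, and 25 of its genes were also on the list fixed beforehand. The third sheets left out genes with an FDR listed as 0, the smallest value in the tables. For 2A against 1A that removed 24 of the 27 photosynthesis genes of the second sheet, with 131 lower and 72 higher genes removed in all. For 4A against 1A it again removed 24 of 27, and for 3A against 2A 20 of 24. No gene encoded by the chloroplast or the mitochondrion was listed in any of the 6 tables. The libraries were of poly-A RNA and only called genes were listed, so this does not show that these genes were unchanged.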
